A study of Mus musculus with 2 samples.

How the data were processed

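Total RNA of C2C12 cells, a mouse myoblast line that forms myotubes when serum is withdrawn, was compared on 2 two-colour arrays of long mouse oligonucleotides. Per the labels, cells of passage 22 were moved to a serum-free synthetic differentiation medium and kept there for 4 h or 24 h, with or without 500 µM GTP. On both arrays the control RNA carried Cy3 and the RNA of GTP-treated cells carried Cy5. There was no dye swap. The design text names 1 control and 1 treated culture, grown independently, with 1 comparison per array. No replicate error can therefore be estimated, no test was run and no p-value is given. The number of arrays limits the precision of every value.

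Per the labels' protocols, RNA was amplified and labelled by a 2-step amino-allyl method. Each deposited scanner table gives the median spot intensity and the local background intensity of each channel at 3 scan settings, named a35, a45 and a55 in the file headers. It also holds background-subtracted intensities combined over the 3 scans by the authors, and the Cy3 intensity multiplied by 1 factor per array, which was 1.523 at 4 h and 1.2525 at 24 h. The deposited ratio column is this scaled Cy3 intensity over the Cy5 intensity, so it runs as control over GTP. A further deposited column holds a mark of 0 or 1 per spot whose meaning is not given in the sources used here. It was set on 19 mouse spots at 4 h and on 7 at 24 h. The authors' value table holds log2 values. They equal the negative log2 of the ratio column at every spot with a value (largest gap 5e-05), and so run as GTP over control, on a log2 scale, centred on a mean of 0 and with no correction for intensity or position. Their medians were 0.05 at 4 h and 0.01 at 24 h. How the 3 scans were combined and the scanner software are not given in the sources used here.

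Each array has 10368 spots in 32 blocks: 384 empty spots, 104 spots of 2 Arabidopsis control oligonucleotides and 9880 mouse spots. The mouse spots hold 9853 probes, of which 9 were printed 4 times. Probes were named through the accession or symbol in the file and a table of mouse genes of assembly GRCm38.p6, used for names only. A single symbol was found for 5693 probes (57.8%), 5271 of them by accession, 213 by current symbol and 209 by an older symbol. The other 4160 probes stay unnamed here. No genome build is named in the sources used here, so no coordinates are printed.

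The a45 scan was corrected for background with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 (R 4.3.3), with control spots and marked spots at weight 0 in the loess. The log2 ratio is GTP over control throughout. Marked spots were left out and repeat spots of a probe were averaged. A signal was taken as well above background when, after subtraction, it passed the 95th percentile of the empty spots of that channel and array. The written rule put a mark of the scanner and the SD of the local background first, but the mark has no stated meaning and no such SD was used here, so its next choice applies. These limits were 49.0 (Cy3) and 179.6 (Cy5) at 4 h and 43.9 (Cy3) and 127.9 (Cy5) at 24 h. Counts and names rest on probes that pass in both channels of each array used. For the control channel at 24 h against 4 h, the channel values followed from loess and Aquantile normalization, and the count rests on probes that pass in the control channel of both arrays. Each array is also its own slide, so time and slide cannot be told apart there.

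A change was counted when the log2 ratio was at least 1 in size, that is 2-fold. The rules for names and lists were fixed before the data were examined. At each time the 12 genes with the highest and the 12 with the lowest log2 ratio are named. For the difference between the times and for the control channel it is 6 and 6. The probe must have 1 symbol, pass in both channels of each array used, and have repeat spots of 1 sign. Within each of 21 gene lists, the first 2 measured members as written and up to 2 with the largest log2 ratio in size are named. Some members of the lists and some repeated probes that this rule covers are not reported here. Other list members quoted below were chosen after their values were seen. Up to 3 brightest probes per direction that pass in only 1 channel are given as bounds. The bound sets the bright channel against the higher of the dim channel's own value and the lowest value that passes in that channel, and is open to dye bias. A gene is the mean of its well measured probes. Of 17 genes with several such probes at 4 h, 10 had probes of opposite sign, and at 24 h this held for 2 of 9. A list is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size drawn from the same intensity deciles. With 1 array per time this describes these arrays only. Medians past the 2.5th or 97.5th percentile are called outside, which 5% of random lists are by construction. The list medians for the difference between times and for the control channel were added after the data were examined.

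The steps were tested on simulated data. They used the real layout, intensities and dye curves, a spot error of 0.4 (SD, log2), 200 changed probes per array and 1 shifted list. Of well measured probes made 3-fold higher, 94.0% passed 2-fold at 4 h and 87.2% at 24 h. Of those made 2-fold higher, 44.0% and 54.0% passed. Lowered probes were lost more often to the background limit: of 50 made 3-fold lower, 37 at 4 h and 32 at 24 h were well measured, against 50 and 47 made 3-fold higher. Of these lowered ones, 78.4% and 93.8% passed, and of well measured probes made 2-fold lower 48.7% and 46.3%. A list of mitochondrial respiration genes shifted by 0.5 had a median at the 100th percentile on both arrays. Among probes with no simulated change, 1.16% of 6804 passed 2-fold at 4 h and 1.04% of 6551 at 24 h.

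The alternatives tried were no background correction, plain subtraction, normexp with offset 0, median centring, print-tip loess, other probe filters, a 1.5-fold threshold, the brightest probe per gene, and the authors' value table. The control channel was also scaled by quantiles. After the data were examined, the combined 3-scan intensities, the a35 and a55 scans, and a count without the last 3 rows of each printed block were added. When the intensity processing changed, the set of probes was kept. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.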

Results

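Gene expression was measured in C2C12 mouse myoblasts after 4 h and 24 h in a serum-free differentiation medium, with and without 500 µM extracellular GTP. Each time had 1 array, on which control RNA (Cy3) and RNA of GTP-treated cells (Cy5) were hybridised together. The median background-subtracted signal of mouse spots was 297 in the control channel and 424.5 in the GTP channel at 4 h, and 212.5 and 232 at 24 h. In the control channel 97.4% of the 9880 mouse spots were well above background at 4 h and 96.2% at 24 h. In the GTP channel, where the empty spots were brighter, it was 74.4% and 68.9%. Both channels passed for 7319 probes at 4 h and 6754 at 24 h. No value below has a biological replicate.

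The spread between spots was measured on the arrays themselves. An Arabidopsis control oligonucleotide printed 52 times had log2 ratios with an SD of 0.43 at 4 h and 0.48 at 24 h. The largest deviation of such a spot from their median was 1.32 at 4 h and 2.08 at 24 h. Over all well measured mouse probes the SD was 0.39 and 0.41. The 9 mouse probes printed 4 times had a pooled SD between spots of 0.40 on both arrays. A single probe is therefore read with a technical error about as large as the spread of all probes, and most named genes rest on a single spot per array.

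The comparison at 4 h asks which transcripts differ early in differentiation when GTP is present. At this time 118 of 7319 probes (1.61%) differed at least 2-fold, 86 higher and 32 lower with GTP. In the simulation with unchanged probes and a spot error of 0.4, 1.16% passed. Of the 52 Arabidopsis control spots 2 (3.85%, exact 95% interval 0.469 to 13.2) lay beyond 2-fold of their median. The simulated share depends on the error chosen, which was the same at every intensity and under the SD of the control spots (0.43). Whether 1.61% exceeds spot error can therefore not be judged from it. The split depends on which probes are counted: among all unmarked probes 157 were higher and 218 lower, and among probes brighter than the median 8 were higher and 26 lower. Among bright probes, Grem1, a secreted BMP antagonist, was 2.66-fold higher. The other highest genes gave dimmer spots. Uros, an enzyme of haem synthesis, was 3.83-fold higher, and M1ap, Rbm4, Kcna2 (a voltage-gated potassium channel), Tlr6 (an innate immune receptor), Eps8, F2rl2 (a receptor of the thrombin receptor family), Ubl4b, Clec4e, Otub2 and Adcy7 (an adenylate cyclase) lay between 2.59-fold and 3.09-fold higher. Of the 12, 8 were at least 2-fold higher in the authors' table, where Kcna2 had 0.43, Adcy7 0.64 and Rbm4 0.80. Of these 12 genes, 8 lay in the last 3 rows of their printed blocks, which held 10% of the measured spots and had a larger SD (0.49 against 0.37 in the other rows). Spots in these rows were also dimmer (median log2 intensity 8.62 against 9.28).

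The lowest genes at 4 h were brighter, and all 12 were measured on both arrays. Of these 12, 5 lay in the last 3 rows of their printed blocks. Mrc2, an endocytic collagen receptor, was 2.65-fold lower with GTP. Ahsg, Kcnip2 (a partner of voltage-gated potassium channels), Slc29a3 (a nucleoside transporter), Il9r, Hoxc4, Prtn3, Dxo, Sh2d2a, Lama3 (a laminin chain), Gucy1b1 (a subunit of the soluble guanylate cyclase, which makes cyclic GMP from GTP) and Mfng (a glycosyltransferase that modifies Notch) lay between 2.05-fold and 2.48-fold lower. With median centring instead of loess all 12 stayed below 0, 6 of them at least 2-fold. In the authors' table all 12 were below 0 and 5 at least 2-fold, with Slc29a3 at -0.23 and Il9r at -0.55 the nearest to 0.

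**Figure D1:**
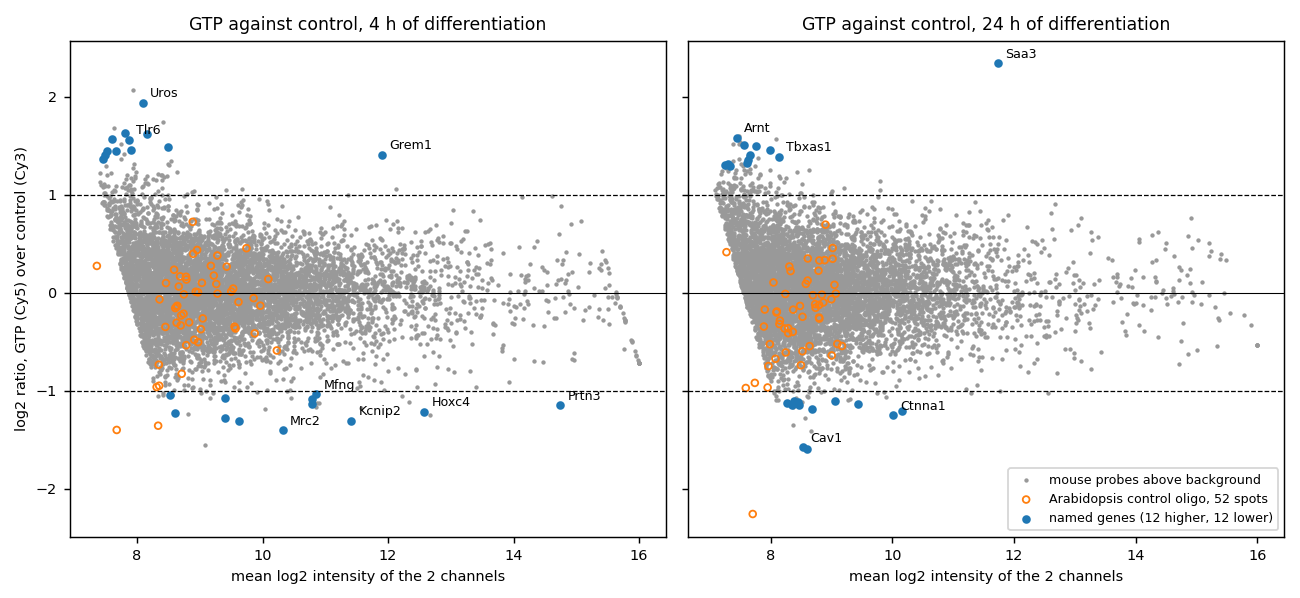
Log2 ratio of GTP over control against the mean log2 intensity of both channels, at 4 h (left) and 24 h (right); grey points are well measured mouse probes, blue points the 12 highest and 12 lowest named genes, orange circles the 52 spots of an Arabidopsis control oligonucleotide, and dashed lines mark 2-fold. Most of the highest genes sit at the dim end, apart from Grem1 at 4 h (1.41) and Saa3 at 24 h (2.34), and the control spots spread with an SD of 0.43 and 0.48.

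Among the gene lists, 3 of 19 had a median outside the range of random lists at 4 h, against 0.95 expected by construction. Genes of the TGF-beta, BMP and Notch pathways were lower with GTP in 12 of 17 measured members, with a median of -0.28 (percentile 0.185). Tgfb2 had -0.79, Jag1 (a Notch ligand) -0.63, Tgfb1 -0.60, Fst (follistatin, an activin and myostatin antagonist) -0.53, and Bmp2 -0.37. Notch2, Inhba and Ltbp1 were above 0. Genes of cell cycle exit were higher in 7 of 10, with a median of 0.33 (percentile 98.0). Rb1 had 0.81, Cdkn1a (p21) 0.39, Ccng1 0.37 and Cdkn2b 0.29. Cytosolic ribosomal proteins had a small negative median of -0.08 (percentile 1.94), with 22 of 34 lower, among them Rpl35 at -0.72, Rpl10a at -0.29, Rpl10 at -0.28 and Rpl7a at -0.26. The median of this list was above 0 with median centring (0.11) and in the authors' table (0.23), which leave the median of well measured probes at 0.11 and 0.09, and its percentile there was 0.16 and 5.60. No member of these lists was 2-fold changed. In the authors' table the medians of the TGF-beta, BMP and Notch list and the exit list fell at the 23.0th and 78.9th percentile, and with the combined scans at the 11.7th and 78.0th. The ribosomal list had a percentile of 12.2 there, so with the combined scans none of these 3 lists was outside. The exit list was also inside with no background correction (97.2) and with median centring (95.5).

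The other lists had medians within the random range at 4 h. Genes of the immediate early and MAPK response had a median of 0.20 (percentile 96.1, and 91.1 to 99.6 over the alternatives), with Fos at 0.49, Fosb at 0.27 and Atf3 at -0.94. Purinergic receptors and ectonucleotidases, a list that also holds nucleoside transporters and adenosine kinase, had a median of 0.18 (percentile 83.0, and 46.0 to 96.8 over the alternatives), which was -0.02 over all unmarked probes. Of its 8 measured members 4 were higher and 4 lower. P2ry1 had 0.84, P2rx7 0.48 and P2rx1 0.40, while Entpd1 had -0.21 and P2ry4 -0.14. Purine nucleotide metabolism had -0.16 (percentile 10.5, which was 34.0 in the authors' table and 33.7 with median centring). Hprt, which salvages guanine and hypoxanthine, had -0.71, and Impdh1, which commits purines to guanine nucleotide synthesis, was near 0. Myogenic regulators had -0.10 (percentile 27.1), with Id3, an inhibitor of myogenic bHLH factors, at -0.70, Myf5 at -0.28 and Mef2a at 0.07. Sarcomere and contractile proteins had -0.01 (percentile 33.7), with Tnni1 at -0.98, Actn2 at -0.37 and Myh4 at 0.51. Cell fusion and adhesion had 0.05 (60.5), with Neo1 at 0.75, Itga7 at 0.70, Vcam1 at 0.53 and Cdh15 at -0.07. Calcium handling had -0.02 (33.6), with Calr, an ER calcium-binding chaperone, at 0.98, Capn1 at 0.62, Atp2a2 at 0.37 and Casq2 at -0.41. Membrane channels had 0.02 (34.9), with Kcna2 at 1.57, Kcnma1, the large-conductance calcium-activated potassium channel, at 0.52 and Kcnmb1 at -0.17.

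The remaining lists at 4 h were also inside. Cell cycle progression had a median of -0.08 (percentile 9.38, and 8.82 to 40.8 over the alternatives), with Mcm6 at -0.66. The insulin-like growth factor pathway had 0.15 (85.3), with Igf2 at -0.32. Extracellular matrix had -0.01 (32.0), with Hspg2 at 0.72 and Col1a2 at -0.33. Heat shock and unfolded protein response had 0.05 (56.2), with Hsp90b1 at 0.75 and Pdia4 at 0.71. Glycolysis had -0.02 (36.5) with Eno3 at -0.97, protein breakdown 0.04 (48.7), mitochondrial respiration 0.08 (74.9) with Atp5e at -0.92 and Cox7b at 0.88, and adipocyte markers -0.07 (32.8) with Cebpb at 0.73. Bone and cartilage markers, with 1 measured member, and markers of cells not expected in the culture, with 2, had too few for a percentile. The signs of these small medians depend on the centring of the arrays, so lists are compared by percentile across scalings.

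The comparison at 24 h asks the same question a day into differentiation. Here 151 of 6754 probes (2.24%) differed at least 2-fold, 117 higher and 34 lower with GTP. In the simulation of unchanged probes 1.04% passed, and 1 of the 52 control spots (1.92%, interval 0.0487 to 10.3) lay beyond 2-fold. The simulated error of 0.4 was under the SD of the control spots (0.48), so an excess over spot error cannot be judged from this share either. Here too the split turned over all unmarked probes (186 higher, 284 lower) and among probes brighter than the median (19 and 30). Saa3, an acute-phase serum amyloid protein, stood apart from all other named genes. It was the sole well measured probe at 24 h past the largest deviation of a control spot (2.08). It was 5.08-fold higher with GTP from a bright spot, and 2.09-fold higher at 4 h. Over the main and 9 other settings of background, scaling and scan, its log2 ratio was 2.14 to 2.55 at 24 h and 0.85 to 1.37 at 4 h. The other highest genes were dim. Arnt, the partner of the aryl hydrocarbon receptor and of hypoxia-inducible factors, had 1.59, and Trp53inp1 (a p53-inducible stress protein), Cyp2c55, Tcea2, Npy1r, Tbxas1 (thromboxane synthase), Hcrt, Ccnc (cyclin C), Slc12a9, Ubr1 (a ubiquitin ligase of the N-end rule) and Gabrr1 lay between 2.46-fold and 2.85-fold higher. Cyp2c55 had 0.10 without background correction, and Hcrt 0.19 in the authors' table. The spots of Npy1r and Slc12a9 were bright at 4 h (mean log2 intensity 10.3 and 9.81) and dim at 24 h (7.67 and 7.31). Their control channel was 5.62-fold and 5.08-fold lower at 24 h than at 4 h. Npy1r, Slc12a9 and Ubr1 shared a block of the slide, Arnt and Trp53inp1 shared another, and the rest of the highest genes lay in other blocks. A local difference on the slide was not tested.

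The 12 lowest genes at 24 h were all measured on both arrays. Cav1, the coat protein of caveolae, was 2.98-fold lower with GTP, and Ctnna1 (alpha-catenin, which ties cadherins to actin) was 2.38-fold lower. The uncharacterised 2310039H08Rik was 3.02-fold lower. The MAGE family gene 4930550L24Rik, Car4 (a carbonic anhydrase), Fam20c (a kinase of secreted proteins), Lhx2, Psmb6 (a catalytic proteasome subunit), Mttp, Dcakd, Efnb3 (an ephrin) and Ntsr1 lay between 2.15-fold and 2.31-fold lower. On the slide, 2310039H08Rik, Cav1, Ctnna1, 4930550L24Rik, Fam20c and Psmb6 all lay in row 8 of the blocks. The rest of the 12 lay in other rows of blocks. Whether position adds to these values was not tested. Of the 12, 8 were at least 2-fold lower in the authors' table. Cav1 was near 0 there (-0.08) and with the combined scans (-0.11), Fam20c had -0.41 in both, and Mttp was above 0 in both (0.21 in each).

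None of the 19 lists with at least 3 measured members had a median outside the random range at 24 h. Sarcomere and contractile proteins came near the lower limit, with a median of -0.22 (percentile 3.70) and 9 of 12 members lower with GTP. Mybph (myosin-binding protein H) had -0.83, Mylpf (a fast myosin light chain) -0.77, Tnni1 (slow troponin I) -0.74 and Actn2 -0.62. This median passed below the 2.5th percentile over all unmarked probes (-0.37, percentile 0.16), in the authors' table (-0.30, percentile 0.85) and with the combined scans (-0.31, percentile 1.00), and lay between 3.77 and 3.83 under the other alternatives. Heat shock and unfolded protein response had -0.24 (percentile 3.20), with 12 of 13 lower. Hsp90b1 had -0.89, Hsph1 -0.54 and Ddit3 -0.29, and the percentile was 1.70 to 3.94 over the alternatives. Glycolysis had -0.22 (3.54), with Pgk1 at -0.77, Eno3 at -0.55 and Hk1 at 0.67, and its percentile was 1.32 to 10.7 over the alternatives. Calcium handling had -0.14 (3.37, which was 21.0 with median centring). Among myogenic regulators (-0.14, percentile 21.0), Id3 was 2.02-fold lower, Myf5 had -0.62, and Pax7, measured at this time only, had 0.48.

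Purinergic receptors and ectonucleotidases lay near the upper limit at 24 h, with a median of 0.26 (percentile 94.8) and 7 of 10 higher, including Entpd5 at 0.85 and P2rx1 at 0.24, while P2rx7 had -0.22. TGF-beta, BMP and Notch genes had -0.15 (5.17), and a percentile of 59.4 in the authors' table and 50.8 with the combined scans, with Bmp2 at -0.66, Fst at 0.79, Tgfb2 at 0.19 and Mstn at 0.05. Purine nucleotide metabolism had 0.10 (72.1), with Impdh1 at 0.46, Gmpr2 at -0.91 and Rrm2 at -0.80. Protein breakdown had -0.10 (12.5, and 2.03 to 18.5 over the alternatives), with Psmb6 at -1.13, Psma1 at -0.86 and Fbxo32, a ubiquitin ligase of muscle atrophy, at 0.74. The other medians were -0.11 for cell fusion and adhesion (11.1, Cdh15 at -0.67), 0.00 for membrane channels (19.3, Trpc1 at 0.98), 0.10 for cell cycle progression (73.3, Ccna2 at -0.62 and Mcm7 at 0.52), 0.09 for cell cycle exit (61.3, Ccng1 at -0.78 and Cdkn2b at 0.63) and 0.11 for the insulin-like growth factor pathway (79.9, Gsk3b at 0.94). They were -0.06 for extracellular matrix (23.9, Col1a2 at 0.52), -0.10 for the immediate early response (15.9, Srf at 0.85), 0.04 for ribosomal proteins (66.9, Rpl7a at -0.78), -0.03 for mitochondrial respiration (29.5, Cox7a1 at 0.83) and 0.07 for adipocyte markers (63.4, Cfd at 0.31). Bone markers and markers of unexpected cells had 1 measured member each.

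**Figure D2:**
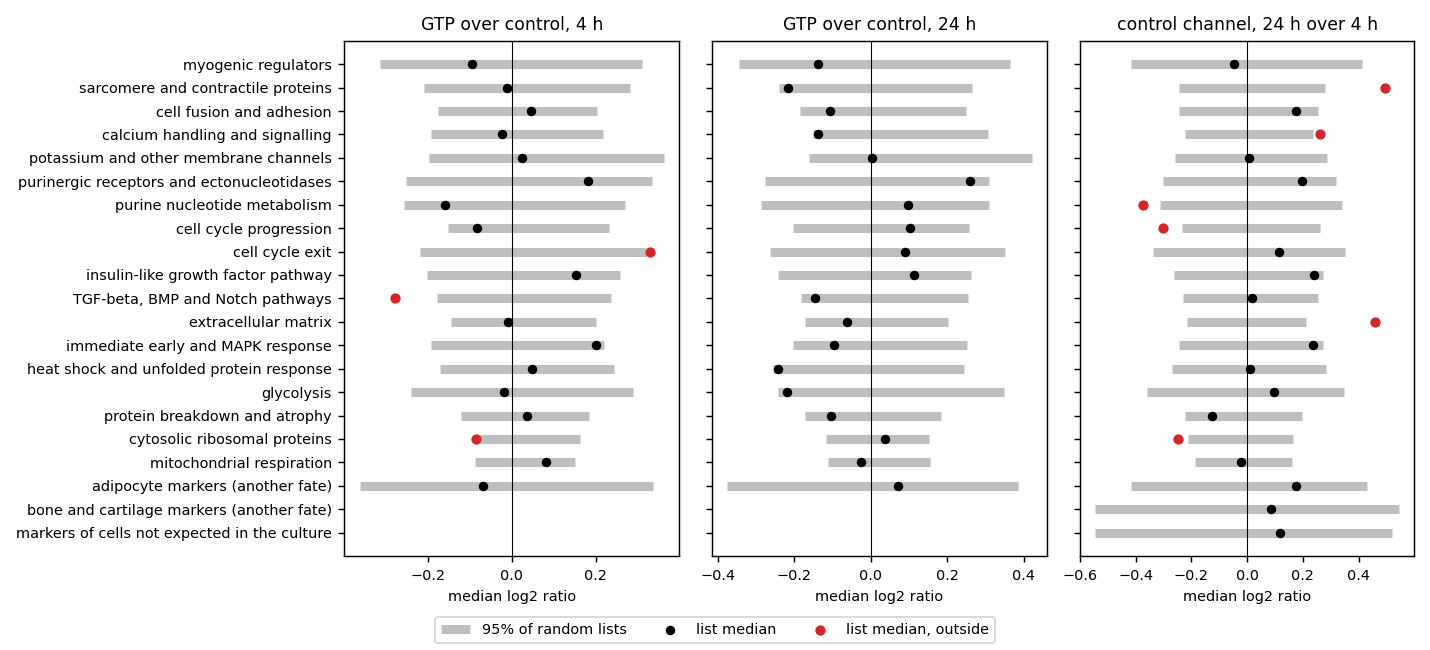
Median log2 ratio of each gene list for GTP over control at 4 h (left), at 24 h (middle) and for the control channel at 24 h over 4 h (right); grey bars hold 95% of 10000 random lists of like size and intensity, and red points lie outside them. At 4 h 3 medians lie outside, at 24 h 0, and in the control channel 6.

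The third comparison asks whether the GTP effect differs between the times. A dye bias that is fixed for a probe cancels here. Of 5993 probes measured on both arrays, 187 (3.12%) had log2 ratios at least 1 apart, 102 higher and 85 lower at 24 h. No simulated share of unchanged probes was made for this count. Il9r (2.06, and 1.03 in the authors' table), Pex11a (1.77, a peroxisome biogenesis factor, and 0.73 there), Slc29a3 (1.68, and 0.84 there), Vsir (1.42), Ccnc (1.39) and Fst (1.31, and 0.33 there) had the largest shifts upward, and all 6 were below 0 at 4 h and above 0 at 24 h. Ndp (-2.03), Tlr6 (-1.94), Hsp90b1 (-1.64, an ER chaperone), Ackr3 (-1.40, a chemokine receptor), Sf1 (-1.39) and Ncdn (-1.37) had the largest shifts downward, from above 0 to below 0. For comparison, the difference between the arrays had an SD of 0.46 over the 5993 mouse probes and of 0.64 over the Arabidopsis control spots. The control spots thus spread wider than all these mouse probes, whose spread holds their own error, so they are a poor measure of that error. A comparison of spreads also cannot judge single probes. With 1 array per time, a time-dependent GTP effect cannot be told from spot error here. The list of ribosomal proteins had the sole median outside the random range, at 0.14 (percentile 97.9), and heat shock genes had -0.31 (percentile 2.98).

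Across these 5993 probes the log2 ratios of both arrays correlated weakly, with a Pearson r of 0.26 (95% interval 0.23 to 0.28, across probes, which are not independent replicates) and a Spearman correlation of 0.23. The sign was the same in 57.7%. At least 2-fold higher at both times were 2 probes, against 0.25 if the calls were independent, and at least 2-fold lower were 4, against 0.155. The named genes among these 6 were Saa3, Mrc2 (-1.40 at 4 h and -1.01 at 24 h) and Mfng (-1.04 and -1.06), named here after their values were seen. Shared dye bias of a probe would also place it in both lists. Mrc2 and Mfng, but not Saa3, lay in the last 3 rows of their printed blocks. Those rows held more than their share of 2-fold spots on both arrays. Whether print row plays a part in these repeats was not tested.

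The control channels at 24 h and 4 h compare cells without GTP at both times of differentiation, with time and array confounded. Sarcomere and contractile genes had a median of 0.49 (percentile 99.97), with 9 of 16 higher and 5 at least 2-fold higher at 24 h. These 5 were Tnnc2 (2.88-fold), Mylpf (2.86-fold), Tnni2 (2.56-fold), Myom2 (2.26-fold) and Tnnc1 (2.03-fold), all components of the contractile apparatus. Extracellular matrix genes had 0.46 (percentile 100), with 17 of 24 higher, among them Dcn (2.84-fold), Eln (2.55-fold), Mmp2, Thbs2 and Col1a2 (2.37-fold). Calcium handling had 0.26 (98.5), with Cacna1s, the pore of the muscle L-type calcium channel, at 1.32, and the list's percentile was 96.9 with quantile scaling, 97.0 over all unmarked probes and 97.4 with median centring. Cell cycle progression was lower at 24 h, with a median of -0.30 (0.83) and 13 of 18 lower, including Top2a (-0.95), Mcm5 (-0.91), Mcm7 (-0.90) and Ccna2 (-0.68). No member was 2-fold lower. The other 5 were higher, among them Kif11 (1.00, the sole 2-fold change) and Cdc25c (0.80). Purine nucleotide metabolism had -0.38 (1.11), with 6 of 11 lower and 5 higher. Rrm2 had -0.80, Gmpr2 -0.78 and Hprt -0.38, and Adssl1 had 0.51, Rrm1 0.31 and Impdh1 0.17. Ribosomal proteins had -0.25 (0.80), with 24 of 34 lower, and 10.5 as percentile with median centring.

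The other 15 lists were inside the random range in the control channel. Their medians were -0.05 for myogenic regulators (percentile 39.9), 0.17 for cell fusion and adhesion (91.0), 0.01 for membrane channels (50.2), 0.20 for purinergic receptors and ectonucleotidases (88.2), 0.11 for cell cycle exit (76.9), 0.24 for the insulin-like growth factor pathway (96.0) and 0.02 for TGF-beta, BMP and Notch genes (54.8). They were 0.24 for the immediate early response (95.5), 0.01 for heat shock genes (52.4), 0.10 for glycolysis (72.5), -0.13 for protein breakdown (15.4), -0.02 for mitochondrial respiration (46.4), 0.17 for adipocyte markers (79.2), 0.09 for bone and cartilage markers (62.1) and 0.12 for markers of unexpected cells (68.5). In all, 619 of 9290 probes were at least 2-fold apart, 326 higher and 293 lower at 24 h. Among probes measured in both channels, Prelid1 was 28.9-fold higher, followed by Pde6b, Ivl, Stxbp4, Pkib and Slc44a4 at 8.71-fold to 14.1-fold. Prelid1, Stxbp4 and Slc44a4 shared a block of the slide, Pde6b and Ivl shared another, and Pkib lay in the block beside that. A local difference between the slides was not tested. Rcn2 was 20.8-fold lower, followed by Zfp33b, Hes3, Spag1, Npy1r and Ifrd1 with log2 ratios of -3.81 to -2.48. These lowest genes each lay in a different block, and Npy1r lay in the block of Pde6b and Ivl. The GTP channel of the same spots moved with the control channel (r of 0.75 across probes). Both channels share the spot and the time in differentiation. The 9 probes printed 4 times had a pooled SD of 0.38 in this comparison.

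Repeat spots gave a technical error for 9 genes. Hprt was the gene whose 4 spots at 4 h lay farthest from 0, with -0.71 ± 0.28 (SD, n = 4 spots of 1 array), that is 1.64-fold lower with GTP, and -0.21 ± 0.39 at 24 h. Rps29 had -0.31 ± 0.27, Actb -0.27 ± 0.45 and Odc1, the enzyme that starts polyamine synthesis, 0.27 ± 0.44 at 4 h. Gapdh had -0.36 ± 0.31 and Actb -0.27 ± 0.26 at 24 h. The 4 spots were of 1 sign for Hprt and Rps29 at 4 h and for Gapdh and Ywhaz at 24 h.

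Some transcripts passed the background limit in a single channel. In the GTP channel alone this held for 10 probes at 4 h and 26 at 24 h. All of them had a bound of at least 2-fold, which the higher limit of the GTP channel favours. The brightest were Angptl1 (at least 3.10-fold higher), Nxph1 (at least 3.05-fold) and Klrc3 (at least 3.02-fold) at 4 h. At 24 h they were Mmp13, a collagenase (at least 4.03-fold), Pmaip1, the p53 target Noxa (at least 3.60-fold) and Dlc1 (at least 3.36-fold). In the control channel alone it was 2281 probes at 4 h and 2724 at 24 h, since the limit was higher in the GTP channel. Of these, 7 had a bound of at least 2-fold at each time. The brightest were Rdh5 (at least 2.72-fold lower), Cntnap1 (at least 2.34-fold) and Abca4 (at least 2.33-fold) at 4 h, and Cdk16 (at least 2.48-fold lower), Faf1 (at least 2.42-fold) and Sipa1 (at least 2.24-fold) at 24 h. Each rests on 1 spot.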

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

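The signs at both times were compared by a fixed rule, and the look at the control spots was chosen only after the data were seen.

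Among the 113 named genes measured on both arrays, 22 had log2 ratios of opposite sign at 4 h and 24 h that lay at least 1 apart. With 1 array per time the difference was not tested for any of them, and no biological explanation was tested. As 24 h minus 4 h, the values were higher at 24 h for Il9r (2.06), Pex11a (1.77), Slc29a3 (1.68), Vsir (1.42), Ccnc (1.39), Fst (1.31) and Zfp33b (1.05). They were lower for Ndp (-2.03), Tlr6 (-1.94), Hsp90b1 (-1.64), Ackr3 (-1.40), Sf1 (-1.39), Ncdn (-1.37), Dcakd (-1.30), Ctnna1 (-1.27), Prelid1 (-1.24), Calr (-1.17), Psmb6 (-1.17), Ivl (-1.15), Lhx2 (-1.15), Ccng1 (-1.14) and Hspg2 (-1.02). Most of these genes are named because their values were extreme, which favours large gaps. Arabidopsis control spots, which carry no mouse sequence, differed between the arrays with an SD of 0.64, and the mouse probes measured on both arrays with 0.46.

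The Arabidopsis control spots gave a signal above the limit set by empty spots. Oligonucleotide 014 had a median background-subtracted signal of 357.8 (Cy3) and 482.2 (Cy5) at 4 h, and of 296.8 (Cy3) and 302.5 (Cy5) at 24 h, against limits of 49.0, 179.6, 43.9 and 127.9. Oligonucleotide 015 passed in Cy3, with 59.5 at 4 h and 53.2 at 24 h, and lay under the limit in Cy5 (60.8 and 48.2). Whether matching RNA was added is not given in the sources used here, and the source of this signal was not tested.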

How the results depend on the processing

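The combined scans, the a35 and a55 scans and the count without the last block rows were chosen after seeing the data; the other alternatives were planned. Causes were not tested, except where the construction of an alternative gives them.

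With 118 probes at least 2-fold apart at 4 h, 151 at 24 h and 187 between the times, plain background subtraction gave 298, 410 and 391. Normexp with offset 0 gave 269, 380 and 350. By construction, neither adds the offset of 50 of the main setting, which shrinks the log2 ratios of dim spots. How much of the rise this accounts for was not tested. The authors' table gave 320 between the times, and the combined scans 229 at 24 h. Scan a35 gave 44 at 4 h and 27 at 24 h, and scan a55 gave 217, 271 and 328. By construction, a filter or threshold changes the number of probes: all unmarked probes gave 375, 470 and 952, those brighter than the median 34 and 49, and 1.5-fold gave 888, 1047 and 1201, and 2114 in the control channel (619 at 2-fold). The other alternatives were within 1.5 times the count.

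The share of higher probes depends on the setting. It was 72.9% at 4 h and 77.5% at 24 h, 63.6% and 64.5% in the authors' table, 20.5% and 22.2% with scan a35, 39.6% and 44.3% with scan a55, and 41.9% and 39.6% over all unmarked probes. The cause was not tested for the scans.

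Of the gene lists, 3 medians were outside the random range at 4 h and 24 h together, against 6 over all unmarked probes and 1 in the authors' table. The ribosomal median at 4 h (-0.08) was 0.11 with median centring and 0.23 in the authors' table, where well measured probes have a median of 0.11 and 0.09. Its percentile of 1.94 was 0.16 and 5.60 there, and 12.2 with the combined scans (median -0.02), so it was inside the random range in the last 2; the cause was not tested. Mttp at 24 h (-1.12) was 0.2124 in the authors' table and 0.205 with the combined scans; the cause was not tested. Of the values of named genes under alternatives, 204 stayed near, 34 moved and 2 turned their sign. The correlation of the arrays ranged from 0.19 (median centring) to 0.26. The signal over background in Cy5 limits dim genes: 74.4% of mouse spots passed at 4 h and 68.9% at 24 h.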

Other observations

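The test of position on the slide was chosen before its result was seen; the other tests of this part, and the list of inflammatory genes, were chosen only after the results were seen.

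More probes were 2-fold higher than lower with GTP at both times. With the same ratios and no background limit, 41.9% of 375 2-fold probes were higher at 4 h (exact 95% interval 36.8 to 47.0) and 39.6% of 470 at 24 h (35.1 to 44.2). Unchanged probes in the simulation also gave more higher than lower (45 and 34 at 4 h, 49 and 19 at 24 h), so the unequal background limits of Cy3 and Cy5 may account for part of the excess. On the same probes, scans a35 (9 higher, 35 lower at 4 h; 6 and 21 at 24 h) and a55 (86 and 131; 120 and 151) turned the split, for which the cause was not tested. Whether GTP raises more transcripts than it lowers stays open. Among probes brighter than the median 23.5% and 38.8% of the 2-fold probes were higher. All 2-fold probes were only 0.691% and 0.995% of these bright probes. In the simulation 1.16% and 1.04% of unchanged probes passed, but these were well measured probes of all intensities with the same spot error. No simulated share for bright probes alone was made, so spot error among them cannot be judged. Loess also centres the ratios at each intensity.

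The log2 ratios of both arrays correlated across probes (0.26). After subtraction of the mean of the surrounding spots r was 0.24 (95% interval 0.22 to 0.27), which argues against position on the slide as the whole cause. A fixed dye bias of each probe and a shared GTP effect cannot be told apart at r of 0.2565, because both arrays have the same dye orientation.

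Saa3 had the highest log2 ratio at 24 h (2.34). At 4 h it lay 2.83 SD above the 200 probes of nearest intensity, which argues against a spot defect on 1 slide as the whole cause. A fixed dye bias of the probe stays open: 24 h minus 4 h was 2.98 SD of such probes, under the 4 SD asked of a gene picked as extreme. A wider acute-phase and inflammatory response might include Saa3; among 32 listed genes, chosen without Saa3, Il6, Grem1 and Ackr3, 10 were measured at 4 h (10 higher, median 0.18, percentile 81.1) and 9 at 24 h (7 higher, median 0.14, percentile 81.4), so it stays open. Mmp13, also listed, passed the background limit in the GTP channel alone at 24 h (at least 4.03-fold higher) and is not in that median. All 26 probes that passed in that channel alone had a bound of at least 2-fold, since its limit was higher. The bound of Mmp13 therefore does not bear on this question. Il6 itself was 2.35-fold higher at 4 h and had 0.09 at 24 h.

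The last 3 rows of the printed blocks held 10% of the measured spots but 29.2% of the 2-fold spots at 4 h (35 of 120), and 9.77% and 23.8% at 24 h (36 of 151). Their SD was 0.49 against 0.37 at 4 h and 0.50 against 0.40 at 24 h. They were also dimmer, with a median log2 intensity of 8.62 against 9.28 at 4 h and 8.24 against 8.74 at 24 h. Position and intensity were not told apart.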
